A study of Mus musculus with 3 samples.

How the data were processed

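Chromatin immunoprecipitation with sequencing (ChIP-seq) was done for Utf1 in KH2 cells, an established line of mouse embryonic stem cells, grown in medium with 15% serum. The series holds 3 samples in 3 groups, with 1 library per group: a precipitation of biotin-tagged Utf1, a precipitation of endogenous Utf1, and a whole-cell extract without precipitation. Per the labels' protocols, chromatin was crosslinked for 5 min in 1% formaldehyde, quenched with 125 mM glycine and sheared to 200 to 700 bp, and fragments of 300 to 600 bp were selected for the libraries. The protocol describes streptavidin beads for the biotin precipitation, whereas the antibody label of both precipitations names the same Utf1 antibody. The library labelled as biotin-tagged is therefore called the biotin list and the other the endogenous list, after their tag labels.

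The deposited files are 2 peak lists, 1 per precipitation, so peaks were listed per library and not on pooled samples. The build is mm9 and the tools BWA 0.5.7 and R 2.15.2 are named, without their roles, per the submitters' processing notes. The peak caller, its settings and the control it used are not given in the sources used here. No values of the whole-cell extract were analysed here. The deposited lists give the tag count of each peak, as whole numbers not scaled for depth, per the file headers and values. The strength of each peak is given as 10 times the −log10 of a p-value, per the file headers, and 1488 biotin peaks and 36 endogenous peaks stand at the value 3100. The deposited fold enrichment is a linear ratio per peak, and the false discovery rate is a percent, both per the file headers. Width and summit position, counted from the start of the peak, are in bp per the file headers. All of these are the authors' own values for a peak and were used to describe, rank or filter peaks within a list. Where medians of both lists are set side by side, or ranks over overlapping pairs are correlated, this describes the lists and measures no change between them.

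Total library depth is unknown, since only tags inside peaks are listed: 14128799 in the biotin list and 276084 in the endogenous list. These sums move with how much sequence was listed, 212 Mb and 7.38 Mb, and are not library sizes. A difference in depth, in enrichment or in caller settings would each change the length of a list.

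Peaks were counted as shared where they overlapped by at least 1 bp. The shares carry exact Clopper-Pearson intervals at 95%, and tag counts carry exact Poisson intervals. All intervals cover counting error only, since reads without molecular identifiers are not independent molecules and neighbouring peaks are not independent. With 1 library per group there is no replicate check and no p-value across peaks is given. The overlap was set beside 1000 circular shifts of the endogenous list within each chromosome, whose length was taken as the largest listed end, and beside 8 shifts by 10, 20, 50 and 100 kb to either side, which keep each peak in its own region. The shifts by 10 to 100 kb, the split by regional peak density, and the descriptions of summit distances and of merged stretches were added after the lists had been examined. Summits within 250 bp and merging within 1 kb had been set before, but only as alternative settings. Peaks up to 1 kb apart were merged into stretches. Peak density was counted in windows of 1 Mb. Peaks on Y and on unplaced sequence were kept unless stated.

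The overlap procedure was tested on simulated lists of 10506 peaks with the widths of the endogenous list. With nothing planted, 1155 simulated peaks overlapped a biotin peak against a mean of 1174 over shifts, a ratio of 0.984. With 20% of peaks planted on biotin peaks, 3018 overlapped, a ratio of 2.57. Simulated peaks that were not planted were placed uniformly along each chromosome, so a ratio near 1 was fixed beforehand for them. This tested the calculation, and not whether circular shifts suit lists that are uneven along the chromosomes. The counts of overlapping peaks, 1971 endogenous and 1950 biotin, were checked with bedtools 2.31.1 and were identical. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

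The rule for named regions was fixed before the data were examined, as were the tests and most of the other settings. It took the 10 shared regions with the smallest sum of ranks in both lists, the 10 strongest biotin regions without an endogenous peak and the 10 strongest endogenous regions without a biotin peak, ranked by fold enrichment and leaving out unplaced sequence. The alternatives were other criteria for sharing, stricter thresholds, lists without the widest peaks or without Y and unplaced sequence, and ranking by other columns. A gene annotation of mm9 was not used here, because the reference at hand names another assembly, GRCm38.p6. The position of peaks relative to genes, the 10 gene lists with 253 genes and the peaks at named genes, Utf1 included, were for this reason not analysed here, and regions are given by their mm9 position alone.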

Results

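Utf1, undifferentiated embryonic cell transcription factor 1, is a chromatin-associated protein of pluripotent cells. Its sites in KH2 mouse embryonic stem cells were listed from 2 precipitations, one of biotin-tagged and one of endogenous Utf1, each with 1 library. The design sets the tagged against the endogenous protein, so the comparisons were how much each precipitation recovered, where in the genome, and whether at the same places. Coordinates are mm9, 1-based, and fold enrichment and tags are the values listed by the authors.

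The biotin list was far longer than the endogenous list, and its peaks were wider and had more tags. It held 152608 peaks over 212 Mb, against 10506 peaks over 7.38 Mb in the endogenous list, 14.5 times as many peaks and 28.7 times the sequence. The median biotin peak was 1085 bp wide (interquartile range 852 to 1599), with 53 tags (34 to 108) and a fold enrichment of 4.14 (3.28 to 6.03). The median endogenous peak was 597 bp wide (578 to 665), with 14 tags (13 to 16) and a fold enrichment of 1.57 (1.37 to 1.76). The largest fold was 30.84 in the biotin list and 4.96 in the endogenous list. The listed 10 times −log10 p had closer medians, 154 and 120.1. The background behind each fold is not given in the sources used here, and in the endogenous list the p-values were far smaller than tags and fold alone would give, so folds of the 2 lists may not be on the same scale.

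Most endogenous peaks lay near the lower limit of their list. The smallest tag count was 13, and 4243 peaks (40.4%) had exactly that count. Up to 15 tags were listed for 7364 peaks (70.1%), a fold under 2 for 9456 (90.0%) and a fold under 1 for 346 (3.29%). The listed false discovery rate reached 9.54% in the endogenous list and 0.5% in the biotin list, and 69 endogenous peaks stood at or under 0.5%. The smallest listed 10 times −log10 p was nearly the same, 50.01 in the biotin list and 50.06 in the endogenous list. The lists therefore began at about the same p-value, but not at the same tag count or false discovery rate. Their lengths do not measure the number of sites occupied.

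Along the chromosomes the 2 lists had different distributions. Biotin peaks were densest on chromosome 11, with 91.6 per Mb, and among autosomes sparsest on chromosome 3, with 39.1 per Mb. Chromosome X held 15.2 per Mb. Endogenous peaks were spread more evenly over the autosomes, from 2.81 per Mb on chromosome 11 to 4.60 per Mb on chromosome 4, and chromosome X held 3.38 per Mb. Chromosome X carried 1.66% of biotin peaks (95% interval 1.60 to 1.73) and 5.36% of endogenous peaks (4.94 to 5.81). Chromosome 11 carried 7.31% (7.18 to 7.45) and 3.26% (2.92 to 3.61). The number of biotin peaks per endogenous peak ran from 4.51 on chromosome X and 8.56 on chromosome 3 to 32.6 on chromosome 11.

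**Figure D1:**
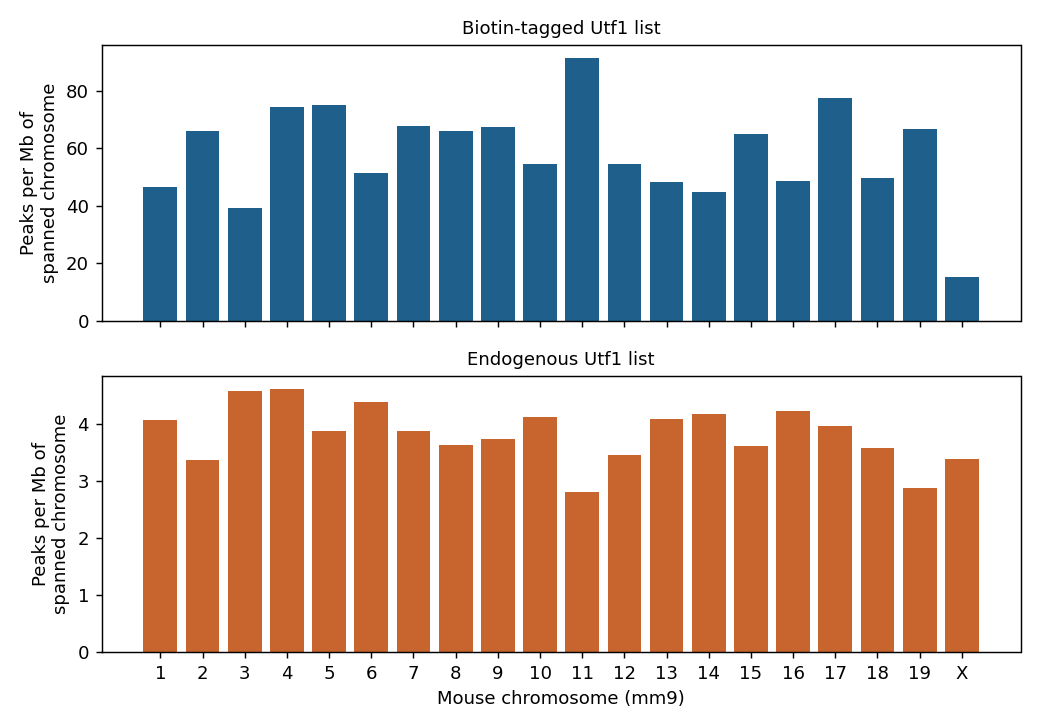
Peaks per Mb of spanned chromosome (vertical axes) for each mouse chromosome in mm9 (horizontal axis), in the biotin list (upper panel) and the endogenous list (lower panel), 1 library each. Chromosome 11 has the highest bar of the biotin list, 91.6 per Mb, and the lowest bar of the endogenous list, 2.81 per Mb.

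The same held at a finer scale. In 2399 autosomal windows of 1 Mb, Spearman's rho between the peak counts of the lists was −0.33 across windows, which are not independent. Windows in the lowest quintile by biotin peaks, with a median of 10, held 4.15 ± 2.54 endogenous peaks (SD over windows). The next quintile, with a median of 19 biotin peaks, held 5.90 ± 5.05. The highest quintile, with a median of 157 biotin peaks, held 2.46 ± 2.38.

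Y and unplaced sequence held 331 endogenous peaks (3.15%), with 20.3% of the tags in that list, and 571 biotin peaks (0.374%). Both lists had a peak with very many tags and little enrichment on chromosome 17. In the biotin list it spanned 39979342 to 39985969, with 10420 tags and a fold of 1.47, and in the endogenous list 39979436 to 39986231, with 4648 tags and a fold of 0.82. The endogenous peak with the most tags, 5880, lay on chromosome 1 at 24618198 to 24623575 and had a fold of 0.79.

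About 1 in 5 endogenous peaks lay on a biotin peak, more than after shifting, while most endogenous peaks had no partner. Of 10506 endogenous peaks, 1971 overlapped a biotin peak, which is 18.8% (18.0 to 19.5). Circular shifts gave a mean of 1171 (range 1016 to 1308), and 0 of 1000 shifts reached the observed number, a ratio of 1.68. Shifts by 10 to 100 kb gave a mean of 812 (729 to 911), a ratio of 2.43. From the other side, 1950 of 152608 biotin peaks, 1.28% (1.22 to 1.34), overlapped an endogenous peak, a share held low by the shortness of the endogenous list. At the strictest threshold no excess was detectable: of the 69 endogenous peaks listed at a false discovery rate of up to 0.5%, 6 overlapped a biotin peak, against a mean of 8.27 (0 to 20) over circular shifts and of 4.5 (2 to 8) over shifts by 10 to 100 kb.

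The strongest regions shared by both lists were led by chromosome 17, 56560939 to 56569006, with a fold of 13.1 and 976 tags in the biotin list, where an endogenous peak at 56566450 to 56567110 had a fold of 2.93 and 17 tags (95% interval 9.90 to 27.2). On chromosome 18, 66092401 to 66095683 had a biotin fold of 14.98 and an endogenous fold of 1.96. On chromosome 6, 136950953 to 136952131 had a biotin fold of 11.71 and an endogenous fold of 3.55 with 60 tags (45.8 to 77.2), the largest endogenous values among the 10. On chromosome 11, 85487192 to 85488478 had a biotin fold of 16.2 and an endogenous fold of 1.76. On chromosome 8 there were 2 such regions, 85168201 to 85169466 and 62128008 to 62129689, with biotin folds of 11.55 and 12.4. The others lay on chromosome 6 at 21343445 to 21345333, chromosome 16 at 53824705 to 53826906, chromosome 5 at 41880138 to 41882109 and chromosome X at 94028629 to 94029860. Over the 10 regions the biotin fold ran from 11.2 to 16.2 and the endogenous fold from 1.76 to 3.55. The lowest endogenous fold, 1.76, equals the upper quartile of that list. The endogenous peaks had 13 to 60 tags. Those on chromosome 11 and at 21343445 on chromosome 6 had 13, the smallest count of the list. On chromosome 5 the endogenous peak began at 41881997, near the end of the biotin peak.

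The 10 strongest biotin regions without an endogenous peak lay at least 39.0 kb from any. The strongest of the whole list, on chromosome 3 at 152148468 to 152150168, had a fold of 30.84 and 615 tags (567 to 666). It was followed by chromosome 4, 154535833 to 154539629, with a fold of 28.72, chromosome 5, 122042088 to 122044661, with 25.4, chromosome 6, 96960401 to 96961994, with 25.34, and chromosome 8, 12946487 to 12950346, with 24.82. The remaining 5, on chromosomes 14, 10, 17 and 16, had folds of 22.75 to 24.3. The nearest endogenous peak was up to 900.1 kb away, with a median of 152 kb. Endogenous peaks were sparse, 2.81 to 4.60 per Mb over the autosomes, so such distances alone do not set these regions apart.

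The strongest endogenous regions were outside the biotin list as well. The first was on chromosome 6 at 60636856 to 60637825, with a fold of 4.96 and 52 tags (38.8 to 68.2). Chromosome 10 held 3 of the 10, at 13121405 to 13122499 with a fold of 4.6, at 114173915 to 114174878 with 4.51 and at 94334253 to 94335382 with 4.31. Chromosome 5 held 2, at 46826468 to 46827536 and 80929501 to 80930492, both with a fold of 4.48. The other 4, on chromosomes 3, 17, 4 and 8, had folds of 4.27 to 4.37. The 10 regions had 52 to 100 tags and widths of 913 to 1130 bp, and the nearest biotin peak was 2.32 to 66.6 kb away.

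Between the weakest and the strongest quintile by fold, sharing differed in opposite directions in the 2 lists, which did not hold by width. Neither course was steady. From weakest to strongest, the shares were 1.05, 0.799, 0.888, 1.25 and 2.40% in the biotin list. In the endogenous list they were 23.5, 20.5, 15.7, 16.4 and 17.7%. Among biotin peaks, 1.05% of the weakest quintile by fold and 2.40% of the strongest quintile overlapped an endogenous peak, a difference of 1.35 percentage points (1.14 to 1.56). Among endogenous peaks the share was 23.5% in the weakest quintile and 17.7% in the strongest, a difference of −5.84 points (−8.28 to −3.40), which turned to 6.53 points when peaks were ranked by width. Endogenous peaks with a fold of 3.5 or more overlapped a biotin peak in 5 of 79 cases, 6.33% (2.09 to 14.2), against a mean of 9.89 (1 to 20) over circular shifts and of 9.25 (5 to 13) over shifts by 10 to 100 kb, so a deficit was not detectable. Across the 1999 overlapping pairs, Spearman's rho between the folds of the lists was −0.07, and between their tags 0.11. Pairs are not independent replicates.

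The excess of shared peaks was largest where biotin peaks were sparse and was absent only in the class above 150 per Mb. In windows with up to 10 biotin peaks per Mb, 211 of 1148 endogenous peaks overlapped one, 18.4% (16.2 to 20.7), against a mean of 17.3 peaks (range 14 to 24) after shifts by 10 to 100 kb. With 21 to 40 per Mb the share was 16.7%, against 5.12% after shifts. With 41 to 80 per Mb, 279 of 1523 overlapped, against a mean of 139 (110 to 165). With 81 to 150 per Mb, 264 of 1202 overlapped, against a mean of 211 (189 to 240). Above 150 per Mb, 173 of 558 overlapped, against a mean of 209.5 (187 to 235). On chromosome X, 131 of 563 endogenous peaks overlapped, 23.3% (19.8 to 27.0), 7.13 times the mean of these shifts. On each of the 19 autosomes the ratio was above 1, from 1.15 to 3.48.

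**Figure D2:**
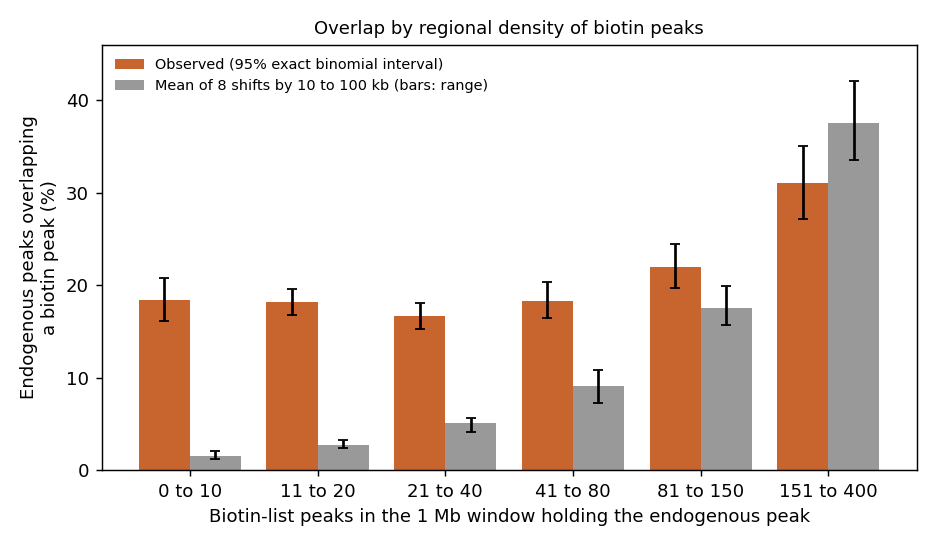
Percent of endogenous peaks overlapping a biotin peak (vertical axis) by the number of biotin peaks in the 1 Mb window around them (horizontal axis), as observed (orange, with 95% exact binomial intervals) and as the mean of 8 shifts by 10 to 100 kb (grey, with their range). In the sparsest class 211 of 1148 peaks overlapped against a mean of 17.3 after shifts, and in the densest class 173 of 558 against a mean of 209.5.

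How closely summits lay together depended on the density of biotin peaks. Over all pairs the median distance between the summits of overlapping pairs was 501 bp (interquartile range 253 to 748), and 495 of 1999 pairs (24.8%) lay within 250 bp, against 23.8 to 26.9% after shifts by 10 to 100 kb. In windows with up to 40 biotin peaks per Mb the share was 20.5% (18.2 to 22.8), against 20.9 to 27.8% after shifts, and in denser windows 31.7% (28.4 to 35.2), against 23.1 to 27.5%. By number, 251 pairs lay within 250 bp in the sparser windows, against 45 to 70 after shifts, and 232 in the denser windows, against 126 to 158. In windows with up to 40 biotin peaks per Mb, endogenous summits were most frequent beside biotin summits: 152 per 200 bp (140 to 165) at 400 to 800 bp, 106 (95.9 to 116) within 400 bp and 60.3 (56.9 to 63.8) at 2 to 4 kb. In denser windows endogenous summits were most frequent on the biotin summit, with 103 (84.1 to 125) in each of the 200 bp bins beside it, 55 and 52 in the next bins, 72.5 per 200 bp (64.4 to 81.3) at 400 to 800 bp and 54.2 (51.0 to 57.5) at 2 to 4 kb.

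**Figure D3:**
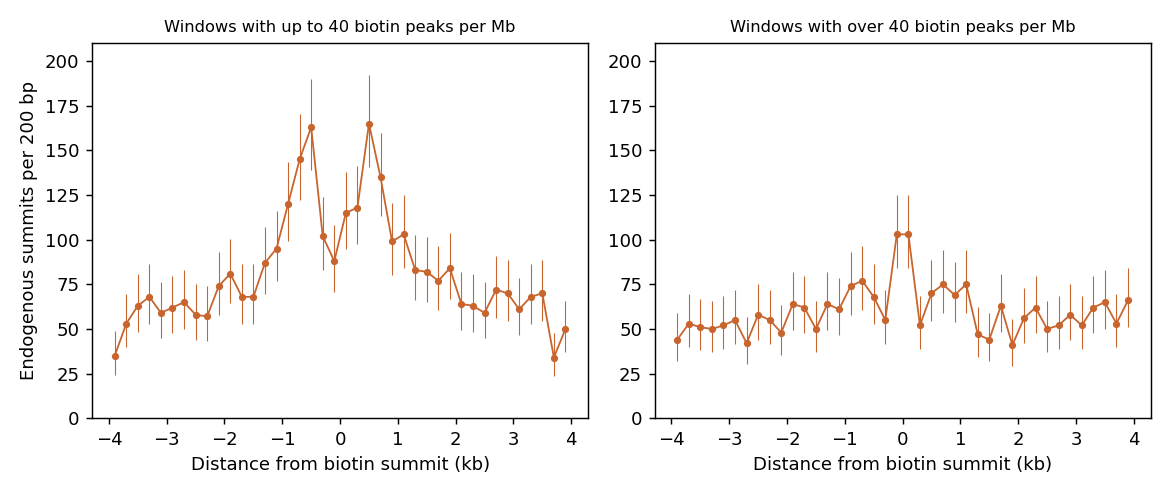
Endogenous summits per 200 bp (vertical axis, with 95% Poisson intervals) by distance from biotin summits in kb (horizontal axis), in 1 Mb windows with up to 40 biotin peaks (left) and over 40 (right). On the left the curve has a peak on either side of the centre, with 152 per 200 bp at 400 to 800 bp and 106 within 400 bp. On the right it is highest at the centre, with 103, and has lower side maxima.

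Merging peaks up to 1 kb apart gave 114916 biotin stretches, of which 247 were longer than 20 kb and 9 longer than 50 kb, unplaced sequence included. The endogenous list gave 10022 stretches, 1 of them longer than 20 kb. The longest biotin stretch was on chromosome 6 at 114438373 to 114587818, 149 kb with 14 peaks, 16559 tags and 111 tags per kb. On placed chromosomes, next came chromosome 12 at 109442017 to 109517447, chromosome 11 at 117893403 to 117966250 and chromosome 8 at 124744518 to 124809520, with 74.1, 67.5 and 77.4 tags per kb. On unplaced sequence, stretches of 68.9 and 38.9 kb had 109 and 106 tags per kb, about the level of the stretch on chromosome 6. Those ranked 2 to 10 on placed chromosomes were 46.8 to 75.4 kb long. Peaks covered 16.0% of equally long flanks of the chromosome 6 stretch and 33.0 to 75.5% of those of the other 9.

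**Figure D4:**
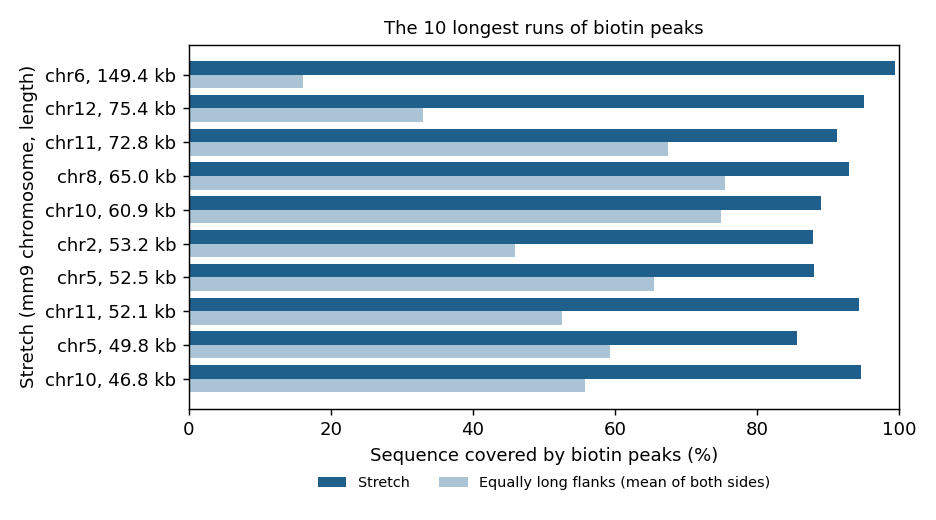
Percent of sequence covered by biotin peaks (horizontal axis) in the 10 longest stretches on placed chromosomes (vertical axis, mm9 chromosome and length), within the stretch (dark) and in equally long flanks (light, mean of both sides). The stretch on chromosome 6 is covered to 99.4% and its flanks to 16.0%, the lowest flank value of the 10.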

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

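The settings for peaks of up to 100 tags or without those of up to 15 tags, for a listed false discovery rate of up to 0.5% in both lists and for shifts by 10 to 100 kb were chosen after seeing the data, and the other settings before. Of 49 alternative values for 12 results, 18 stayed within their error or within 1.5 times the count, 28 moved and 3 reversed. The share of endogenous peaks overlapping a biotin peak, 18.8%, became 12.5% with an overlap of 50% of the shorter peak, 4.71% with summits within 250 bp, 30.3% with peaks within 1 kb, 10.8% for the stronger 50% of each list, 2.62% with the biotin list at the length of the endogenous list, 17.3% without the widest 10%, 21.4% without peaks of up to 15 tags and 8.70% at a false discovery rate of up to 0.5%. In the order of the first 6 settings the biotin share, 1.28%, became 0.839, 0.324, 2.13, 0.742, 2.56 and 1.19%. The ratio to circular shifts, 1.68, became 1.56 with the 50% overlap, 1.60 for the stronger 50%, 2.16 at equal length, 1.98 without the widest 10%, 1.76 without peaks of up to 15 tags and 2.43 with shifts by 10 to 100 kb. The 1.68 rests on 1000 circular shifts, the 2.43 on 8 shifts and the others on 100 circular shifts each. The ratio reversed to 0.680 at a false discovery rate of up to 0.5%, where 69 endogenous peaks remained and the biotin list lost none. There 6 peaks overlapped, against 3 to 21 over 100 circular shifts, and the ratio to shifts by 10 to 100 kb was 1.33. A true reversal was therefore not detectable. The stronger 50% of the lists held 76304 and 5253 peaks by construction.

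Ranked by width, the difference between the strongest and the weakest quintile reversed to 6.53 points in the endogenous list and became 0.357 points in the biotin list, where the 50% overlap gave 0.983. The rank correlation across shared pairs reversed to 0.11 by tags. Chromosome X held 1.46% of the biotin list by covered length and 1.93% for the stronger 50%, and 4.64% of the endogenous list for the stronger 50%. Chromosome 11 held 7.82% of the biotin list by covered length. Apart from the shorter lists, the cause was not tested. With 1 library per group no replicate could be left out. The planned settings for positions relative to genes and for gene lists were not run. Unknown library depth limits every statement on list length.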

Other observations

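All tests in this part were chosen after the result was seen, and no biological explanation was tested, since the design has 1 library per group.

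The first pattern was the local excess of shared peaks. Regional density common to both lists was argued against in windows with up to 80 biotin peaks per Mb. There the ratio to shifts by 10 to 100 kb, which keep the region, was 2.01 to 12.2 by class. With 81 to 150 per Mb it was 1.25, which left the question open, and above 150 per Mb it was 0.826, with no excess to explain. The pooled ratio of 2.43 mixes these classes. High-copy sequence marked by over 100 tags, or by lying on Y or unplaced sequence, did not carry the excess. Without these peaks, 1901 of 10017 endogenous peaks overlapped, against 698 to 874 after the same shifts (ratio 2.45). High-copy sequence with fewer tags on placed chromosomes stays open. Sites called with the same summits in both lists are a candidate explanation in windows with over 40 biotin peaks per Mb, where 31.7% of pairs lay within 250 bp against at most 27.5% after shifts, and stay open in sparser windows, where the share was 20.5% (18.2 to 22.8, against 20.9 to 27.8% after shifts) but 251 such pairs stood against 45 to 70, so the pooled 24.8% decides nothing. Elements of several kb that hold peaks of both lists, such as long repeats, are a candidate source in the sparser windows: the density of endogenous summits 3 to 5 kb from a biotin summit was 1.92 times (1.80 to 2.04) that at 8 to 12 kb, and at 6 to 8 kb 0.900 times (0.821 to 0.986), though these distances were set from the same counts and the sequence was not analysed here. In the denser windows the ratio was 1.04 (0.980 to 1.10), but the excess within 1 kb was itself only 1.44 times, so the test could not decide there. Each endogenous summit was counted against every biotin summit within 12 kb. Where biotin peaks lie close together, 1 endogenous summit can therefore enter at several distances, which these ratios do not separate. The intervals of these density ratios leave out the error of the counts at 8 to 12 kb. In the sparser windows that error was 0.940 to 1.06 times, so 0.900 at 6 to 8 kb was not clearly below 1.

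The second pattern was the run of biotin peaks on chromosome 6 at 114438373 to 114587818. A wider zone of dense peaks stays open. Peaks covered 16.0% of its flanks and at least 33.0% of those of the other 9 longest stretches. The flanks were unlike in length, 149 kb per side against 46.8 to 75.4 kb, so this comparison could not decide. Before the chromosome 12 stretch the coverage was 8.75%, below both sides of the chromosome 6 stretch (20.4 and 11.7%). Extra copies of the chromosome 6 stretch in the tagged cells may account for the run but stay open. Its tags per kb had a coefficient of variation of 3.82% over its 4 peaks of 10 kb or more, and no other stretch had 3 such peaks to compare. Over peaks of at least 5, 3 and 2 kb it was 8.74, 7.66 and 12.7%, and 4 of 28, 8 of 173 and 55 of 417 other stretches were as even. Stretches of 68.9 and 38.9 kb on unplaced sequence had about the same level, 109 and 106 tags per kb, and the whole-cell extract, which could show extra copies, was not analysed here.

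The third pattern was that endogenous peaks with a fold of 3.5 or more showed no excess of overlap, 5 of 79 against 5 to 13 after shifts by 10 to 100 kb. These 79 peaks had 20 to 153 tags (median 72), and 0% had up to 15. They were thus not peaks of the smallest tag counts. The choice by fold had fixed this beforehand, the largest fold with up to 15 tags being 2.74, so counting noise could not be tested in this way. High-copy sequence that collects reads in any library stays open: 0% lay on Y or unplaced sequence or had over 250 tags. Such peaks were also left out by the choice by fold: endogenous peaks over 250 tags had a median fold of 1.49. Sites just under the threshold of the biotin list stay open. Of the 79 peaks, 16.5% had a biotin peak within 1 kb, at the lower end of the range over shifts (16.5 to 27.8). A list holds nothing below its threshold, so the test could not decide.

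The listed p-values and folds had different relations in the 2 lists. Over the 150688 biotin and 10466 endogenous peaks whose listed value was under 3000, and from tags and fold alone, with a Poisson background of tags divided by fold, 10 times the −log10 p had a median of 162 in the biotin list, where 151 was listed, and of 11.6 in the endogenous list, where 120.0 was listed. Summits lay off centre by more than 10% of the width in 77.2% of endogenous peaks with 13 tags, in 48.2% of those with 16 to 20 tags and in 57.7% of those over 50 tags. Over all peaks it was 66.7% in the endogenous and 47.2% in the biotin list, and among peaks of 500 to 700 bp 74.3% and 49.8%.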
